A study of Homo sapiens with 6 samples.

How the data were processed

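RNA was measured in TPC1, an established papillary thyroid cancer cell line, in 6 samples of 2 groups. In 3 samples the cells had received an siRNA against the circular RNA hsa_circ_0000839 (si-circ_0000839), and in 3 a negative-control siRNA (NC), in both cases for 60 h before collection, per the labels. Cells grew in DMEM with 10% serum, total RNA was taken with Trizol and libraries followed the standard Illumina procedure, per the labels' protocols. HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named in the submitters' processing notes. The strand setting, the genome build and the way each library was scaled are not given in the sources used here. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples.

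The authors deposited a table of FPKM (fragments per kilobase of gene and per 1e6 reads) with 58735 genes, the 6 libraries, gene lengths, coordinates and biotypes, per the file headers. All 58735 gene IDs had the same chromosome, start, end and strand in GENCODE release 29, so coordinates are given as GRCh38. For 27 genes the file held a spreadsheet date in place of a symbol, and the symbol of the same gene ID in the reference was used, as for MARCHF4. FPKM times gene length was a whole multiple of a fixed step in each library for 100% of values above 0, within 0.01 of a whole number, which gave the reads per gene. The recovered total was 18399558 to 19334633 reads per library. The total used by the authors for scaling, read from the same step, was 0.958 to 1.02 times the recovered total, lowest in NC replicate 2 and then in si-circ_0000839 replicate 1. No 2 libraries held identical values, and the 6 pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.14 to 10.8 on the recovered reads.

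FPKM values are not counts, so the test was limma 3.58.1 in R 4.3.3 with a trended prior variance on log2(FPKM + 1), two-sided, for genes with a mean of at least 1 FPKM over the 6 libraries, with group as the only term. Log2 changes on this scale understate the change of genes with low values, and folds are ratios of the mean FPKM of the groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower, and a second count asked in addition for a log2 change of at least 1. Gene lists, 35 in all, were fixed before the data were examined, as were the main tests, most alternatives and the rule for named genes. Lists with at least 5 tested genes, 31 in all, were tested with camera of limma at a preset correlation of 0.01, against all other tested genes, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and limma's fry were run beside it. For each list and library, the mean deviation of its members from their mean over the 6 libraries gave a list score, compared between groups with an exact permutation test, whose smallest possible two-sided p for 3 against 3 is 0.1.

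Named genes are the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap. To these were added the 5 most abundant called genes in each direction without mitochondrial genes, up to 3 non-coding genes in each direction, up to 4 called members of each list described or else its member with the smallest p, and RHOA, ZEB1, ZEB2, CDH1, VIM and CDC27. Genes named for another reason were chosen after their values were seen. A few genes and 1 list that these rules take are not reported here.

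The test was tried on simulated reads drawn from the real means and totals. At a true change of 1.25-fold it recovered 14.3% of 49 changed genes, at 1.5-fold 83.3% of 48 and at 2-fold 100% of 48, with 8 false calls among 10671 genes. With limma's voom on the simulated reads the shares were 30.6%, 93.8% and 100%. All simulated genes had the same spread between libraries (dispersion 0.00499), and no simulated library had a trend on GC content or length. The real libraries had such trends, so these shares and false calls can be too favourable for the real data. In another set of simulated reads camera found the 1 shifted list and called 0 of the 30 unchanged lists. Simulated genes varied independently of each other, so this trial cannot show how often camera calls lists of correlated genes. In the real data the estimated correlation was 0.235 for the mesenchymal list and 0.143 for the mitosis list.

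Alternatives were other pseudocounts, no filter or a minimum of 5 FPKM, quantile, TPM and median-ratio scaling, the replicate number as a block, other prior variances, library quality weights, voom on the recovered reads, protein-coding genes alone and each library left out in turn. After the data were seen, 3 more were added: leaving out 2 libraries that stood apart, removing from each library a spline trend (5 degrees of freedom each) on GC content and length, and a minimum mean of 10 reads. For the scan of 3' UTRs in the closing part, the UTR of the GENCODE transcript with the longest coding sequence was taken for each gene, and each word of 7 bases found in at least 100 of the 9580 protein-coding genes that were not called was scored. The score (z) is the difference in log2 change between genes with and without the word, divided by its standard error over genes. Cubic terms in UTR base shares, UTR length, expression, GC content and gene length were removed first. A planted word was recovered by this scan in simulated values. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.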

Results

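Gene expression was profiled by RNA sequencing in TPC1 papillary thyroid cancer cells after silencing of the circular RNA hsa_circ_0000839, to ask which genes change when this RNA is depleted. Of 6 libraries, 3 came from cells that received si-circ_0000839 and 3 from cells that received the NC siRNA, collected 60 h after transfection. The libraries held 18399558 to 19334633 recovered reads and 20533 to 21088 genes with a value above 0. Mitochondrial genes took 1.33% to 1.60% of reads and the 10 most abundant genes 6.67% to 7.09%. Log2 changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values, while folds are ratios of the mean FPKM of the groups. The gene table was not matched to the circular RNA itself, so no value is given for the target in any library and its depletion was not checked here. PAX8, a thyroid lineage factor, was at 96.3 ± 5.26 FPKM (SD, n = 3) after si-circ_0000839 and 95.8 ± 2.21 in NC.

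After si-circ_0000839, a small set of genes moved, mostly by less than 2-fold. LGALS3, which encodes the lectin galectin-3, fell the most, from 10.1 ± 0.926 FPKM in NC to 1.69 ± 0.0372 (SD, n = 3 per group), 5.97-fold. ANKRD52, SELENOF, LCN2 and GOLPH3L fell to about 0.5 times their NC level. Among the largest rises were those of MMP9, a secreted gelatinase, from 1.08 to 3.17 FPKM, and of VGF, SEMA7A and ADAM19, by 1.94-fold, 1.79-fold and 1.70-fold. RHOA stood at 316 FPKM in both groups.

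Of 10674 tested genes, 41 passed an adjusted p of 0.05 in limma, 14 higher and 27 lower, and in all 41 the groups did not overlap. Among all tested genes 18.1% had groups that did not overlap, against 10% by chance. At an unadjusted p under 0.05 there were 1347 genes, where chance gives 533.7, and 1 of the other 9 ways to divide the 6 libraries into 3 and 3 gave 1821. A log2(FPKM + 1) change of at least 1 was reached by 4 of the 41 genes, MMP9 upward and LGALS3, MIR6797 and MIR6835 downward. The share of higher calls depended on scaling: there were 29 higher and 34 lower genes after quantile normalization, 33 and 23 after rescaling to TPM, and 93 and 105 after a trend on GC content and length was removed from each library. Leaving out a single library left between 17 of the 41 calls (without si-circ_0000839 replicate 3) and 29 (without si-circ_0000839 replicate 2).

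**Figure D1:**
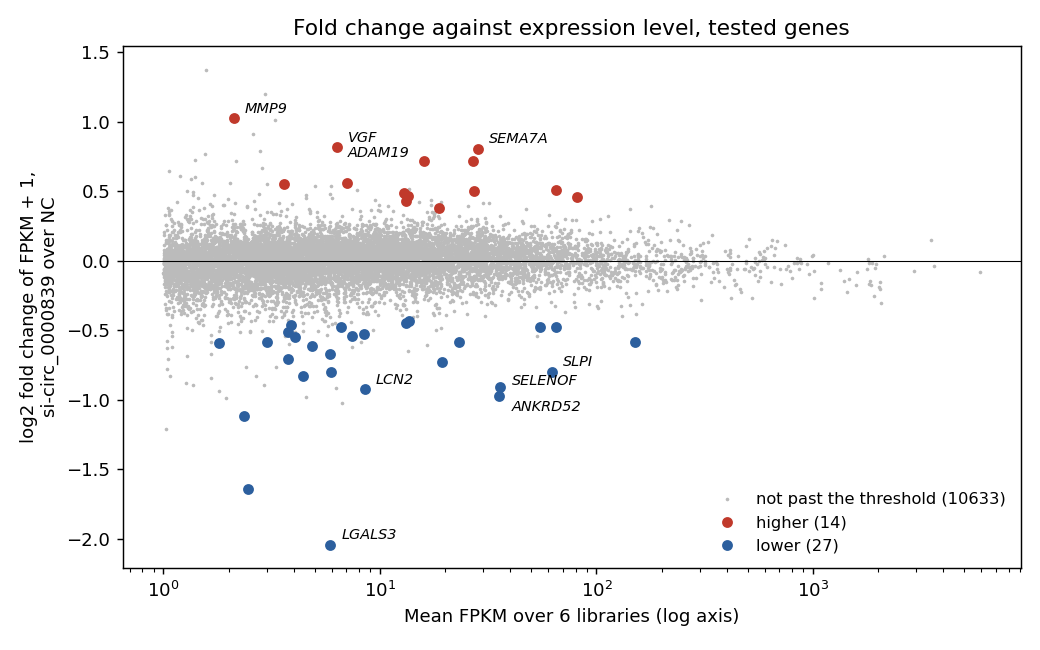
Log2 fold change of FPKM + 1 (si-circ_0000839 over NC) against the mean FPKM over the 6 libraries on a log axis, for the 10674 tested genes. Grey points did not pass the test, red points are the 14 higher and blue points the 27 lower genes; LGALS3 lies lowest at -2.04.

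Genes that rose were of mixed kind. SEMA7A, a membrane-anchored semaphorin, rose from 20.3 ± 0.886 to 36.2 ± 1.32 FPKM (log2 change 0.81, SE 0.07, adjusted p = 0.000474). The metalloprotease gene ADAM19 rose from 11.8 to 20.1 FPKM (adjusted p = 0.00254). VGF, a neuropeptide precursor, went from 4.32 to 8.37 FPKM, and MMP9 had a log2 change of 1.03 (SE 0.13, adjusted p = 0.0110). ITGA5, the fibronectin receptor subunit, rose from 53.3 ± 3.77 to 76.4 ± 5.39 FPKM, TGFBI from 68.4 to 94.7, and the basement membrane collagen gene COL4A1 from 22.3 to 32.1. CNTNAP1, TRAF1 and MARCHF4 were also among the 10 largest rises, at 1.56-fold, 1.64-fold and 1.44-fold. MMP9 missed the threshold without si-circ_0000839 replicate 1 (adjusted p = 0.0579). COL4A1 lies across COL4A2, itself at 33.6 FPKM in NC and 40.4 after si-circ_0000839, on the other strand, and ADAM19 lies across CYFIP2. As the strand setting is not given, reads of such pairs cannot be assigned with certainty.

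Genes that fell were also varied. LGALS3 (ENSG00000131981) lies on chromosome 14 from 55124110 to 55145413, plus strand, GRCh38, and its change was the most certain in the data (log2 change -2.04, SE 0.08, adjusted p = 1.04e-06). It rested on 457 reads per library in NC and 76.3 after si-circ_0000839. ANKRD52, a subunit of protein phosphatase 6, fell from 47.5 ± 4.15 to 23.6 ± 1.49 FPKM, and SELENOF, a selenoprotein of the endoplasmic reticulum, from 46.9 ± 3.20 to 24.5 ± 0.930 (adjusted p = 0.000474 for each). The protease inhibitor genes SLPI and PI3 fell 1.76-fold and 1.68-fold, and LCN2, an iron-siderophore carrier, fell from 11.5 to 5.57 FPKM. GOLPH3L fell 2.03-fold. CTR9, a subunit of the PAF1 complex, fell 1.92-fold, and TAF12, a subunit of TFIID, 1.73-fold. C1QL1 fell 1.70-fold. The most abundant genes that fell were C4orf48, from 180 to 120 FPKM, SLPI, GNG11, IGFBP3 and SELENOF. CTR9 and TAF12 share positions with the expressed genes EIF4G2 and RAB42 on the other strand.

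**Figure D2:**
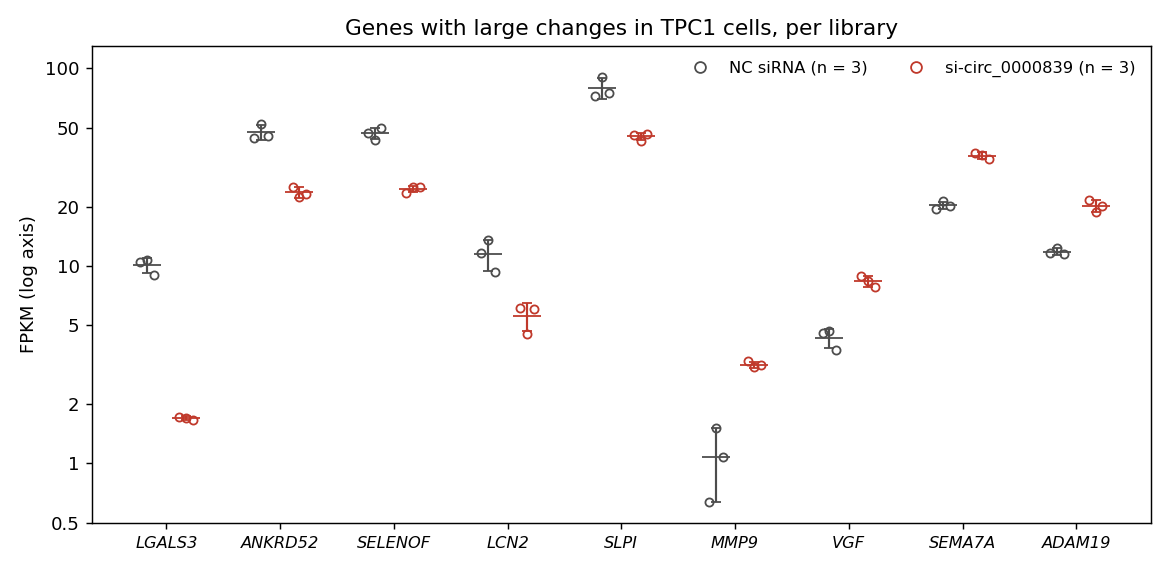
FPKM on a log axis of 5 genes that fell and 4 that rose, with a circle per library, a horizontal line at the mean and bars of 1 SD (n = 3 per group; grey, NC; red, si-circ_0000839). For every gene shown the 3 libraries of each group lie apart, LGALS3 at 9.05 to 10.8 in NC and 1.65 to 1.73 after si-circ_0000839.

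No non-coding gene rose past the threshold, and 3 fell. MIR6797 and MIR6835 were called on a mean of 5.67 and 4.33 reads per library in NC and 1 and 1.33 after si-circ_0000839. They lie inside RPS19 and HMGA1, at 538 and 885 FPKM in NC, so their reads cannot be told apart from reads of the host transcripts, and neither reaches a mean of 10 reads. The processed pseudogene AL031729.1 fell 1.89-fold on 17.7 and 9.33 reads.

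Of 30 genes that the naming rule took from the calls, 12 passed in every fit with 1 library left out, among them LGALS3, ANKRD52, SELENOF, GOLPH3L, SLPI, CTR9, C1QL1, TAF12, VGF, SEMA7A and ADAM19. The other 18 missed the threshold in 1 to 5 of these 6 fits, with adjusted p up to 0.173. ITGA5 had an adjusted p of 0.0842 without si-circ_0000839 replicate 1, 0.0992 without replicate 3, and 0.0897 and 0.108 without NC replicates 1 and 3. For TGFBI the same 4 fits gave 0.0777, 0.0884, 0.110 and 0.125. LCN2 missed narrowly without si-circ_0000839 replicate 1 (0.0521) and without NC replicate 2 (0.0527). IGFBP3, COL4A1, OASL and SCD each missed it in 5 fits, IGFBP3 at 0.0769 to 0.168, COL4A1 at 0.0613 to 0.0863, OASL at 0.0504 to 0.105 and SCD at 0.0847 to 0.173.

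Genes of the mesenchymal state were higher as a group. Of 33 tested members, 3 rose, among them ITGA5 and TGFBI, IGFBP3 fell from 64.0 to 45.9 FPKM, and 29 did not pass. Adjusted over the list alone, 15 were higher and 2 lower. The mean log2 change was 0.15, with 25 members above 0, and the list passed camera (adjusted p = 9.16e-07), though not with an estimated correlation (adjusted p = 0.504). Its score lay above all 3 NC libraries in each si-circ_0000839 library (exact permutation test, two-sided p = 0.1, the smallest possible). The same separation was seen in lists that did not pass camera, such as p53 targets and SWI/SNF subunits, so it is not particular to this list. VIM, a classical member, was at 201 ± 3.86 FPKM against 215 ± 4.81 in NC (adjusted p = 0.590), and ZEB1 and ZEB2 stayed under 1 FPKM at 0.820 against 0.853 and 0.498 against 0.533. The epithelial gene CDH1 had 0 reads in all 6 libraries, in each of which 3 reads would have given at most 0.0267 FPKM. Of the list of epithelial junction genes 14 of 35 were tested and 0 passed, and F11R had the smallest p, at 15.5 against 17.8 FPKM.

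The list of TGF-beta targets, with 24 tested members, was higher in camera (mean log2 change 0.12, adjusted p = 0.00144; adjusted p = 0.505 with an estimated correlation). There were 3 members that rose, among them COL4A1 and TGFBI, and 21 did not pass. Adjusted over the list alone, 7 were higher and 1 lower. The call was also lost without NC replicate 2 (adjusted p = 0.0640). YAP/TAZ targets were also higher (24 tested, 21 above 0, mean log2 change 0.12, camera adjusted p = 0.000154; adjusted p = 0.504 with an estimated correlation). The only member of that list past the threshold over all genes was IGFBP3, a binding protein of insulin-like growth factors, which fell. Adjusted over the list alone, 7 of its members were higher and 1 lower. The mesenchymal list shares members such as TGFBI with the TGF-beta list and IGFBP3 with the YAP/TAZ list, so these lists are not independent.

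Mitotic genes were lower as a group. Of 48 tested members of the mitosis and G2/M list, TTK, a spindle checkpoint kinase, fell from 3.83 ± 0.141 to 2.22 ± 0.240 FPKM, and 47 did not pass. There were 40 members below 0, with a mean log2 change of -0.13, and the list passed camera (adjusted p = 1.05e-06; adjusted p = 0.504 with an estimated correlation). Adjusted over the list alone, 1 was lower. The list score of each si-circ_0000839 library lay below all 3 NC libraries, from -0.15 in replicate 1 to 0.0066 in replicate 2, against 0.05 to 0.08 in NC. Such a separation was also seen in lists that did not pass camera, such as apoptosis regulators and fatty acid synthesis. TTK missed the threshold without si-circ_0000839 replicate 1 (adjusted p = 0.0540), without si-circ_0000839 replicate 3 (adjusted p = 0.0619) and without NC replicate 3 (adjusted p = 0.0788). The DNA replication and G1/S list had a mean log2 change of -0.01, a median of 0.01 and a mean of 0.0054 after rescaling to TPM. Of its 45 members 0 passed the threshold, and camera gave adjusted p = 0.745. In fry's test of change in either direction its adjusted p was 0.00237, against 0.0473 for the mitosis list. In the anaphase-promoting complex list 0 of 15 members passed. CDC27 in that list was at 4.79 ± 0.479 FPKM against 6.32 ± 0.636 in NC (log2 change -0.34, SE 0.09, adjusted p = 0.176).

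**Figure D3:**
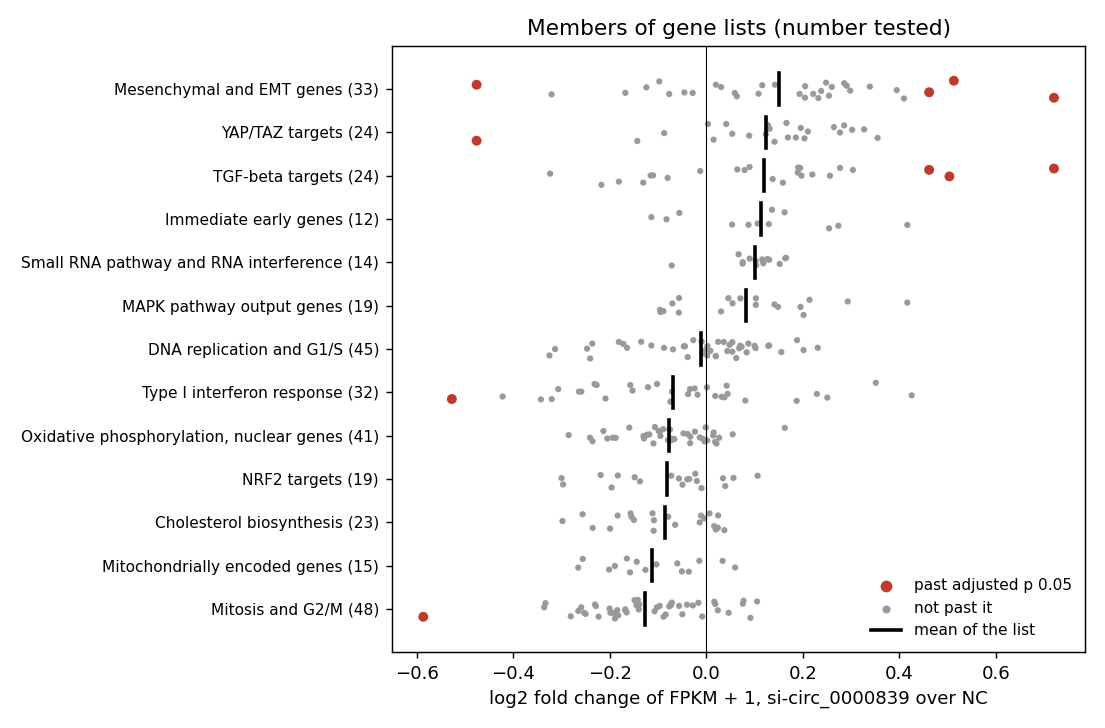
Log2 fold change of FPKM + 1 (si-circ_0000839 over NC) of each tested member of the 12 lists that passed camera and of the DNA replication and G1/S list, with the number tested in brackets. Red points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars are list means, from 0.15 for mesenchymal genes to -0.13 for mitosis.

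Camera called 12 of the 31 lists, 6 higher and 6 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.504. Fry called 0 lists as moving one way and 15 as changing in either direction. Among the 15 were lists that camera did not call, such as DNA replication and G1/S and NF-kappaB (fry adjusted p = 0.00237 and 0.00170). Nuclear oxidative phosphorylation, mitochondrial and cholesterol genes, called by camera, were not among them (fry adjusted p = 0.211, 0.281 and 0.183). Only the mesenchymal, mitosis and YAP/TAZ lists were called in every fit with 1 library left out.

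Small changes without a single called member made up most of the other called lists. Immediate early genes (12 tested, mean log2 change 0.11, adjusted p = 0.0140) and MAPK output genes (19 tested, 0.08, adjusted p = 0.0477) were higher, both with MYC at 36.4 against 27.0 FPKM (adjusted p = 0.0743), and both at adjusted p = 0.505 with an estimated correlation. The small RNA pathway list, which holds the Argonaute and Dicer genes, was higher in camera (14 tested, 13 above 0, mean 0.10, adjusted p = 0.0107; adjusted p = 0.504 with an estimated correlation). None of its members passed, with XPO5 at 9.13 against 8.12 FPKM. NRF2 targets (19 tested, mean -0.08, adjusted p = 0.0175) and cholesterol biosynthesis genes (23 tested, mean -0.09, adjusted p = 0.0107) were lower, each at adjusted p = 0.504 with an estimated correlation, with SRXN1 at 6.03 against 7.65 FPKM and INSIG1 at 13.2 against 16.4. Type I interferon genes were lower (32 tested, mean -0.07, adjusted p = 0.0477; adjusted p = 0.504 with an estimated correlation), and OASL fell from 10.2 to 6.75 FPKM. Without NC replicate 2 the adjusted p rose to 0.0815 for small RNA and cholesterol genes, 0.0852 for NRF2 targets, 0.0815 for immediate early genes and 0.147 for MAPK output. Without si-circ_0000839 replicate 2 the small RNA, cholesterol and NRF2 calls were lost as well. The immediate early and MAPK calls were lost without si-circ_0000839 replicate 1, the MAPK and NRF2 calls without replicate 3, and the MAPK call without NC replicate 1. The interferon call was lost without NC replicate 1 or 3 and without si-circ_0000839 replicate 1 or 2, at adjusted p up to 0.163.

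Nuclear genes of oxidative phosphorylation (41 tested, 33 below 0, mean log2 change -0.08, adjusted p = 0.00144) and the 15 mitochondrially encoded genes (mean -0.11, adjusted p = 0.0107) were lower in camera with no called member. With an estimated correlation both had an adjusted p = 0.628. NDUFB8 was at 5.61 against 7.05 FPKM and MT-RNR2 at 1750 against 2089. The nuclear list rested on NC replicate 2, whose score was 0.15 against -0.05 to 0.00064 in the other 5 libraries, and without it the adjusted p was 0.343. That library also held the highest share of reads on ribosomal protein genes, 9.46% against 8.32% to 8.78% elsewhere. The mitochondrial list had an adjusted p of 0.0904 without it, 0.116 without NC replicate 1, 0.0620 and 0.0803 without si-circ_0000839 replicates 2 and 3, and 0.468 once the GC and length trend was removed.

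The remaining 19 lists with at least 5 tested genes did not pass camera, with adjusted p from 0.172 to 0.940 and means between -0.05 and 0.09. They include cytosolic ribosomal proteins, p53 targets, apoptosis regulators, unfolded protein and heat shock responses, Wnt targets, hypoxia and glycolysis, autophagy, homologous recombination, histones and SWI/SNF subunits. In 17 of them no member passed. The ribosomal protein list, with a mean log2 change of -0.04, passed in opposite directions depending on the libraries: lower without NC replicate 1 (mean -0.09, adjusted p = 0.000473) and without NC replicate 3 (mean -0.06, adjusted p = 0.0187), but higher without both si-circ_0000839 replicate 1 and NC replicate 2 (mean 0.05, adjusted p = 0.0110). SCD, the stearoyl-CoA desaturase of the fatty acid synthesis list, fell from 7.87 to 5.40 FPKM. In the NF-kappaB list TRAF1 rose from 2.72 to 4.47 FPKM and LCN2 fell; its mean log2 change was -0.02 (0.0042 after rescaling to TPM), its median 0.02, and camera gave an upward direction (adjusted p = 0.940). LDHA of the glycolysis list stood at 274 against 334 FPKM (adjusted p = 0.132), and BCL2L2 of the apoptosis list at 4.75 against 6.31 (adjusted p = 0.0743).

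Thyroid function genes were largely silent: 8 of 27 were tested, 0 passed, and TSHR and SLC5A5 had 0 reads in all libraries. Markers of other cell types were few. PTPRC and CD3E of leukocytes had 0 reads, while LCP1 was at 216 FPKM against 210 in NC (adjusted p = 0.864). Among fibroblast markers COL1A1 was at 0.565 against 0.370 FPKM and DCN at 0.0028 in both groups, and LUM was at 15.8 ± 2.40 against 22.5 ± 2.53 (adjusted p = 0.108). ROBO4 of the endothelial list was at 3.71 against 2.72 FPKM (adjusted p = 0.147) and ENO2 of the neuronal list at 18.0 against 16.4.

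Libraries within a group also differed from each other. The first principal component held 34.9% of the variance and placed si-circ_0000839 replicates 1, 2 and 3 at -13.9, 1.63 and -2.56 and NC replicates 1, 2 and 3 at 9.02, -4.66 and 10.4. The second held 27.6%, with si-circ_0000839 at 1.92, 8.68 and 6.91 and NC at -2.00, -13.9 and -1.59. In the fifth of genes with the highest GC content si-circ_0000839 replicate 1 and NC replicate 2 lay above their gene means by 0.11 and 0.08 on the log2 scale. In the fifth with the lowest they lay at -0.14 and -0.05. Without both libraries 26 genes passed, 18 of them among the 41.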

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

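Across 22 alternative settings no called gene among the 58 named genes turned its direction, while RHOA, which was not called, ranged from -0.04 to 0.06. Among the named genes 1093 values kept their side of the threshold, 127 were weaker and 34 stronger. Against the 41 genes changed, there were 4 with no filter on low values, 68 at a minimum of 5 FPKM, 63 with quantile normalization, 66 with a robust prior variance, 120 with voom, 125 among protein-coding genes alone and 1969 with library quality weights, whose estimation stopped short of convergence. Leaving out 1 library gave 20 to 38 genes. With 2 settings chosen after the data were seen, the count was 26 without the 2 libraries that stood apart and 198 after the GC content and length trend was removed. Against the 4 genes with a log2(FPKM + 1) change of at least 1, there was 1 with no filter, 2 at a minimum of 5 FPKM, 2 after rescaling to TPM, 2 with a robust prior variance, 2 among protein-coding genes, 21 with library quality weights and 2 at a mean of at least 10 reads, a setting also chosen after the data were seen. Leaving out 1 library gave 4 to 6. Against the 12 gene lists, leaving out 1 library gave 4 (without NC replicate 2) to 12, and an estimated correlation gave 0. The interferon and MAPK calls also ended at a minimum of 5 FPKM (adjusted p = 0.438 and 0.167), with quantile normalization (0.0866 and 0.0658), with the replicate block (0.0858 and 0.0559) and with camera on ranks (0.0851 and 0.128). The small RNA call ended at a minimum of 5 FPKM (0.195) and the mitochondrial call with quantile normalization (0.288). Without the 2 libraries that stood apart the MAPK, TGF-beta, immediate early and nuclear oxidative phosphorylation calls ended (0.286, 0.127, 0.127 and 0.338), and after removal of the GC content and length trend the MAPK and mitochondrial calls (0.120 and 0.468). The ribosomal protein list, not called, turned from a mean of -0.04 to 0.04 without NC replicate 2. The 2 microRNA genes have a mean under 10 reads and under 5 FPKM and are not protein-coding, which explains their loss under each of those 3 filters. At a minimum of 5 FPKM MMP9, at 1.08 FPKM in NC and 3.17 after si-circ_0000839, was not tested either. The count there therefore includes a gene that was not among the 4. The cause of the other differences was not tested. The replicate number as a block gave 35 genes, 25 of them among the 41. Deviations of equal replicate numbers correlated at -0.15, -0.29 and 0.15, and the best match had the same number only for number 3. These values show no pairing by number, but so few correlations cannot exclude it.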

Other observations

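A scan of 3' UTRs described the falls by sequence. Of 15073 words of 7 bases, ATATCTA went most strongly with lower values after si-circ_0000839, with z = -11.2 over the 9580 protein-coding genes that were not called. The next was TATCTAA (z = -8.75), which shares 6 bases with it, and then GACAATT (z = -4.91). In 256 such genes with ATATCTA followed by A the mean log2 change was -0.11 (SE 0.0094), and 78.5% were below 0. It was -0.03 in 579 genes with the word but without the A, -0.02 in 448 with only its last 6 bases and the A, 0.00032 in 305 with the word in the coding sequence alone and 0.01 in 7992 with none of these. These means are unadjusted. After the terms in base shares, length, expression and GC content used for z were removed, they were -0.08, -0.03, -0.0064 (SE 0.0047), -0.0032 and 0.0049, in the same order. Standard errors and z here are over genes, not over libraries. Per library, genes with the word minus those without lay at -0.10, 0.03 and -0.03 in si-circ_0000839 replicates 1 to 3, relative to the mean over libraries. In NC replicates 1 to 3 the values were 0.07, -0.05 and 0.08, so the groups overlapped. With the same terms removed they were -0.02, -0.02 and -0.03 against 0.03, 0.02 and 0.03, and the groups lay apart. The word was picked as the lowest on this same difference in these same genes. Neither this separation nor the lower means of genes with the word is therefore independent of that choice. Of 24 fallen genes with a 3' UTR, 8 carried the word: ANKRD52, SELENOF, GOLPH3L, CTR9, TAF12, GSKIP, GNG11 and G3BP2. LGALS3, LCN2, SLPI and TTK did not carry it in the UTR searched, nor did any of the 14 genes that rose. Among genes that fell in voom the word was in 33 of 65, against 835 of the 9580 genes not called. The 65 include genes not called in the main test, which helped to pick the word, so their share is not independent of that choice.

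The comparisons of mitosis with G1/S genes and of base composition, and the chance divisions for genes and for genes with a log2(FPKM + 1) change of at least 1, were written down after the result was seen. Dividing the 6 libraries into 3 and 3 in all 10 ways, a count as large as the real 41 genes was reached by 1 division, the real grouping, and the highest other count was 2. For the 4 genes with a log2(FPKM + 1) change of at least 1 it was 1 division, with 2 as the highest other count, and for the 12 lists 1 division, with 10 as the highest other count. With 10 divisions no share under 0.05 can be reached. At an unadjusted p under 0.05 the real grouping gave 1347 genes, and the division that joined si-circ_0000839 replicates 1 and 3 with NC replicate 2 gave 1821.

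For the genes that fell most, a hypothesis is that part of the falls are off-target effects of a short guide whose seed pairs with ATATCTA (z = -11.2). The other divisions had lowest z values of -7.26 to -4.29, most led by the same word, as each keeps 2 of the 3 si-circ_0000839 libraries together. Fallen genes carried the word in 33.3% of cases (95% interval 15.6% to 55.3%) against 8.72% of genes not called (Fisher's exact test, two-sided p = 0.000701). Base composition of the UTR stays open as a part of it: with base shares and GC content left in, ATATCTA had z = -14.8 and the lowest of 129 other words of the same bases had z = -8.60. With them removed, ATATCTA kept z = -11.2, and the lowest of these other words had z = -3.10. The removal shrinks words of the same bases by construction. The z that ATATCTA kept argues against base composition as the whole cause in the genes not called. The siRNA sequence is not given in the sources used here. A microRNA with the same seed, including any that the circular RNA might bind, therefore cannot be told from the siRNA itself. In the UTR searched, 16 of the 24 fallen genes lack the word. That UTR was short in some of them, such as 45 bases in IGFBP3 and 44 in C4orf48. UTRs of other transcripts were not searched.

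For the higher mesenchymal list (mean log2 change 0.151; adjusted p = 0.504 with an estimated correlation), the mean was 0.124 after the trend on GC content and length was removed (camera adjusted p = 2.22e-05 at the preset correlation), so this trend is not its whole cause. Without the 2 libraries that stood apart it was 0.124 (adjusted p = 0.000971). RNA of fibroblasts does not explain it, as 4 of 5 abundant fibroblast transcripts were under 1 FPKM. Without the 5 members with ATATCTA or TATCTAA in the 3' UTR the mean was 0.18. These words were picked for lower values, so leaving out such members tends to raise a mean, and this value does not bear on the cause. An effect of losing the circular RNA was not separated from an effect of the siRNA itself.

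For the lower mitosis list (mean log2 change -0.128; adjusted p = 0.504 with an estimated correlation), the mean was -0.107 after removal of the GC content and length trend (camera adjusted p = 6.39e-06 at the preset correlation) and -0.0931 without the 2 libraries that stood apart (adjusted p = 0.000323). Fewer cells in the cycle as a whole would lower G1/S genes too. The mitosis mean minus the G1/S mean changed by -0.117 (95% t interval over libraries -0.25 to 0.02, n = 3 per group), most in si-circ_0000839 replicate 1, so this explanation stays open. Without the 5 members with ATATCTA or TATCTAA in the 3' UTR the mean was -0.13. Whether the circular RNA or the siRNA lowers these genes was not tested.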
